A study of Homo sapiens with 2 samples.

How the data were processed

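HepG2 cells, an established liver cancer line, were kept in serum-containing medium without treatment, per the labels' protocols. Cells were lysed in a buffer with sodium dodecyl sulfate, chromatin was precipitated with a polyclonal antibody against Twist1, and the purified DNA was sequenced by a company, per the labels' protocols. The labels name 2 groups of 1 library each, the Twist1 ChIP and the input DNA. The series' design text speaks of histone modifications in more than 1 cell type, which differs from the labels of both samples, and the sample labels were followed here. Trim Galore, FastQC and Bowtie2 and the build hg19 are named in the submitters' processing notes, without versions, roles or order. The peak caller, its threshold, any duplicate or blacklist filter and the use made of the input library are not given in the sources used here. All of these can change how many peaks are listed and where.

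The authors deposited 1 peak list, of the Twist1 ChIP library, whose header names a chromosome, a start, an end and a length in bp. Its other 6 columns are empty. Length equalled end minus start plus 1 in all 4137 rows, so positions include both ends. Whether they are counted from 1 is not shown by this. The list holds no fold, score, p-value, summit or read count. Peaks could therefore not be ranked, filtered or tested by strength, and the depth behind each is unknown. Signal of the input library was not used here. Some rows repeat another row exactly: the 4137 rows describe 3570 distinct positions, and each position was counted once.

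The gene table at hand was that of assembly GRCh38.p14, not hg19. The coordinates of the list were checked against it: 229 peaks on 9 chromosomes, 187 of them on chromosome 9, start beyond the last gene of their chromosome in GRCh38.p14, so the list was not read as GRCh38. Beyond this check, no position of one build was set against a position of the other. Peaks were thus not assigned to genes, promoters, exons or introns, and no motif was searched, since an hg19 sequence and annotation were not used here. The gene features, distances to transcription start sites, gene lists, cell type markers and E-box motifs chosen for testing before the data were examined were not analysed, and no gene is named. From the gene table only the number of genes per chromosome was used, with 19970 protein-coding genes (59094 genes of all kinds) on the 22 autosomes and X, and the number per Mb of GRCh38.p14.

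The share of peaks on each chromosome had been planned for comparison with the share of non-gap bases. It was compared instead with the share of protein-coding genes, by an exact two-sided binomial test with Benjamini-Hochberg adjustment over 23 chromosomes and exact Clopper-Pearson 95% intervals. These intervals cover counting error only. Clustering was measured as the share of peaks whose midpoint had another midpoint within 10 kb, against 10000 random placements of the midpoints between the first and the last peak of the same chromosome. Assembly gaps, which had been planned to be left out, stayed in. Strength being absent, length stood in for it: Spearman's rho of length with the number of other peaks within 500 kb, and the difference of the median length of each chromosome with 30 or more peaks from that of all others, both with 100000 permutations. The threshold was 0.05 throughout. With 1 ChIP library, every test describes this list and none compares samples; peaks are not biological replicates.

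Alternatives fixed before the data were examined that the list allowed were merging peaks within 1000 bp and a distance of 100 kb in place of 10 kb. The rule for naming genes, fixed at the same time, needed fold values and gene assignments and could not be applied, so regions and chromosomes are named by their peak counts and lengths, after these were seen. Alternatives chosen after the data were seen were counting every row, keeping peaks longer than the median, counting windows of 100 kb or 1 Mb once, all genes as the reference, placement inside windows of 5 Mb or 1 Mb, other distances, leaving out chromosomes, shifting lengths around each chromosome, and the peaks of chromosome 5 outside its densest window. The gene share as reference, the placement range, length as the stand-in for strength and the regions described were also chosen after the data were seen.

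The procedures were tested on simulated data. With 3570 simulated peaks and 3 chromosomes raised 2-fold, 100% of the raised chromosomes were recovered over 100 data sets, and 0.30% of unchanged chromosomes were called. These peaks were drawn independently of each other, whereas those of the list are clustered. The simulated rates therefore do not give the error rate of the chromosome calls in this list. With the same number of peaks, the clustering test passed the threshold in 2.5% of 40 sets of random positions and in 100% of those with up to 200 planted pairs. The permutation test of a rank correlation was tested on sets of 500 values with 200 permutations each. It passed the threshold in 100% of related sets. Of unrelated sets it passed in 10% of 40 and in 10% of 200, above the nominal rate. The number of sets was then raised to 1000, where it passed in 4.3%, and the test itself was left as it was. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.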

Results

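Binding sites of Twist1 were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in HepG2, an established human cell line derived from a liver cancer. Twist1 is a basic helix-loop-helix transcription factor known for its part in mesoderm development and in the epithelial-mesenchymal transition, the loss of epithelial features by carcinoma cells. Chromatin was precipitated with a polyclonal antibody against Twist1 in 1 library, and 1 library of input DNA from the same line served as the companion sample without antibody. The cells received no treatment. The data set analysed here was the list of Twist1 peaks. Neither library had a replicate, so no value carries a replicate error, and no peak was tested for being found again in a second experiment. The list gives the position and length of each peak without read counts, enrichment or significance, and the sequencing depth behind each peak is therefore unknown.

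The Twist1 list held 3570 distinct peaks on the 22 autosomes and the X chromosome. They were short. The median length was 232 bp (95% order-statistic interval 229 to 235 bp), with quartiles at 195 and 302 bp. Together the peaks covered 972 kb of the genome, and no peak overlapped another. The shortest length was 173 bp, shared by 54 peaks, and 1051 peaks (29.4%) were 200 bp long or less. Only 191 peaks (5.35%) were longer than 500 bp and 9 were longer than 1000 bp. The longest peak, 2075 bp, lay on chromosome 21 at 9825466 to 9827540 (hg19). Any blacklist filter behind the list is unknown, and whether this peak marks Twist1 binding was not tested.

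**Figure D1:**
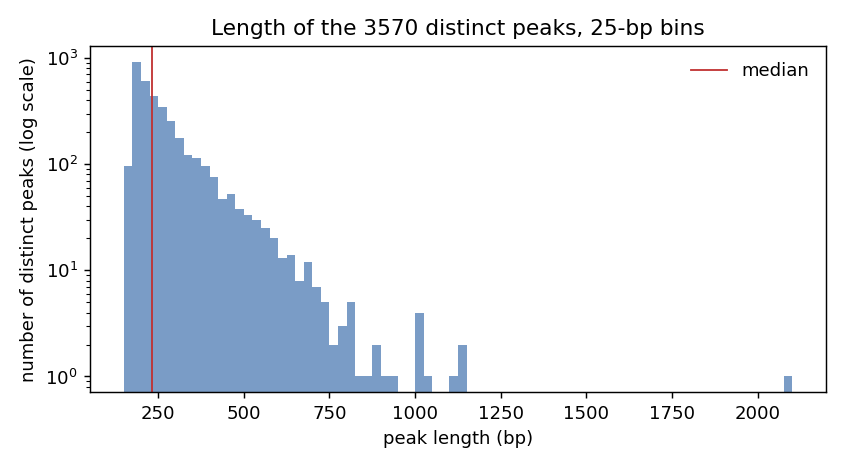
Number of distinct Twist1 peaks (y axis, log scale) by peak length in bp (x axis, 25-bp bins), with the median of 232 bp as a vertical line. Lengths fall off from the minimum of 173 bp, and the single peak of 2075 bp stands apart from the rest.

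Of the 8 other peaks longer than 1000 bp, 4 lay within the first 2 Mb of chromosome 5. They spanned 1887169 to 1888295, 488155 to 489280, 669356 to 670471 and 1295286 to 1296289 in hg19, and measured 1127, 1126, 1116 and 1004 bp. The remaining ones were on chromosome 9 (138590753 to 138591793, 1041 bp), chromosome 1 (1851624 to 1852642, 1019 bp), chromosome 14 (100758746 to 100759764, 1019 bp) and chromosome 10 (46970123 to 46971129, 1007 bp). These peaks were picked by their length after the list had been seen.

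The next comparison asked how the Twist1 peaks were spread over the chromosomes, relative to the genes each chromosome carries. Peaks were far from evenly spread. Chromosomes 5, 7, 9, 16 and 20 together carried 1565 peaks, 43.8% of the list, against 20.1% of the protein-coding genes. At the other end, chromosomes 4, 18 and X together carried 21 peaks (0.588%) against 9.45% of the genes. Per chromosome, an exact two-sided binomial test against the share of protein-coding genes, with Benjamini-Hochberg adjustment over 23 chromosomes, placed 5 chromosomes above their share, 10 below and 8 on neither side. When each 100-kb window with a peak was counted once in place of each peak, the split was 7 above and 6 below. With 1-Mb windows it was 2 above and 4 below, and with all annotated genes as the reference 8 above and 14 below. The binomial test treats peaks as independent, which nearby peaks are not.

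Chromosome 9 had the most peaks. Its 422 peaks were 3.03 times the number expected from its genes (95% exact binomial interval 2.77 to 3.32, adjusted p = 1.17e-86 by the exact binomial test). Chromosome 20 carried 198 peaks, 2.06 times its share (1.79 to 2.36), and chromosome 5 carried 331, 2.05 times its share (1.84 to 2.27). The ratios of chromosome 7 (323 peaks, 1.93, interval 1.73 to 2.14) and chromosome 16 (291 peaks, 1.91, interval 1.70 to 2.13) were close to these. The densest 5-Mb window of each held 57.4% of the peaks of chromosome 5, 62.2% of those of chromosome 16, 55.6% of those of chromosome 20, 46.7% of those of chromosome 9 and 25.1% of those of chromosome 7. With the peaks of that window left out and its genes still in the expected number, which lowers every ratio by construction, chromosomes 7 and 9 stayed above 1, at 1.44 and 1.62. Chromosomes 5, 16 and 20 were then at 0.87, 0.72 and 0.92, so an excess outside the window was not shown by these values. For chromosome 9 the windows on both sides, with 70 and 74 peaks, were left in. Of its 422 peaks, 341 lay beyond 130 Mb, and 139 were expected on the whole chromosome. An excess outside that dense end was therefore not shown for chromosome 9 either. With each 1-Mb window counted once, chromosomes 5 and 7 were still called above their share, at 1.69 and 1.74. Chromosomes 9, 16 and 20 had ratios of 1.07, 1.07 and 1.06 and were not called. The number of such windows is capped by chromosome length, while the reference is the share of genes. This raises the ratios of gene-poor chromosomes and lowers those of gene-dense ones. Chromosomes 5 and 7 carried 4.98 and 5.89 protein-coding genes per Mb, and chromosomes 16 and 20 carried 9.47 and 8.35. The contrast between these 2 pairs therefore cannot be read as a difference in how widely peaks were spread. Chromosome 9, with 5.62 genes per Mb, lay between chromosomes 5 and 7, so gene density does not account for its lower window ratio. Its 422 peaks occupied 41 such windows, against 75 and 80 for the 331 and 323 peaks of chromosomes 5 and 7.

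The lowest ratios belonged to the X chromosome (7 peaks, 0.046, interval 0.019 to 0.095), chromosome 4 (10 peaks, 0.073, interval 0.035 to 0.134) and chromosome 18 (4 peaks, 0.083, interval 0.023 to 0.212). These 3 chromosomes were called below their share under all 6 alternative settings, with ratios of at most 0.14, 0.21 and 0.23, reached with each 1-Mb window counted once. Chromosome 6 followed with 58 peaks and a ratio of 0.31 (0.24 to 0.40), chromosome 22 with 36 peaks and 0.45 (0.31 to 0.62), and chromosome 2 with 118 peaks and 0.53 (0.44 to 0.63). With each 1-Mb window counted once these were 0.68, 0.63 and 0.99 and no longer passed the threshold. That count follows chromosome length and not genes, which raises the ratio of a gene-poor chromosome such as 2 (5.18 genes per Mb). It would lower that of chromosome 22 (8.88 genes per Mb), whose call was lost with 14 windows counted (interval 0.35 to 1.06). A lost call therefore does not show that the deficit is gone. Chromosomes 3, 10, 12 and 19 were called below their share by smaller margins, with ratios from 0.66 to 0.81. None of these 4 was called with each 100-kb window counted once, where their ratios were 1.07, 1.06, 0.85 and 0.84. With 1-Mb windows chromosomes 3, 10 and 12 were at 1.19, 1.25 and 0.96 and again not called, and chromosome 19, dense in genes, has too few such windows to reach its share of genes. With all annotated genes as the reference, chromosome 19 was instead called above its share, at 1.20. Chromosomes 1, 11, 14 and 17, with 367, 229, 104 and 218 peaks, had intervals that included 1, as did chromosomes 8, 13, 15 and 21. With all annotated genes as the reference, chromosomes 11 and 17 of these were called above their share and chromosomes 8, 13, 14, 15 and 21 below.

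**Figure D2:**
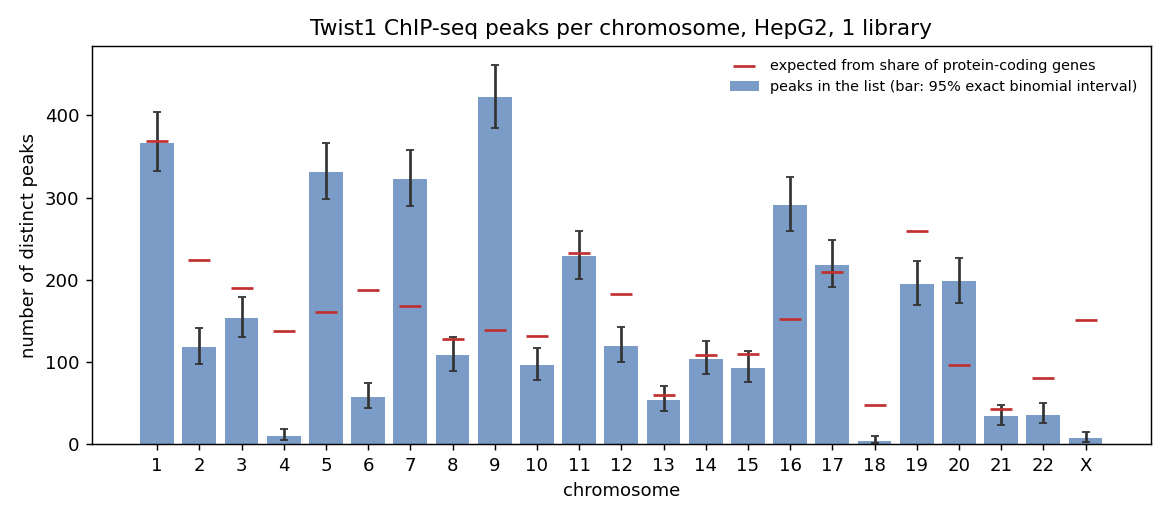
Distinct Twist1 peaks per chromosome in the 1 ChIP library (bars, y axis from 0) with 95% exact binomial intervals, which cover counting error only, and the number expected from each chromosome's share of protein-coding genes (red marks). Chromosomes 5, 7, 9, 16 and 20 stand above their marks, and chromosomes 4, 18 and X hold 10, 4 and 7 peaks.

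Across the 23 chromosomes, the number of peaks rose with the number of protein-coding genes (Pearson's r = 0.53, permutation p = 0.0092; Spearman's rho = 0.59, permutation p = 0.0035; both two-sided). Adjusted over these 2 coefficients, the permutation p-values were 0.0092 and 0.0070. After chromosomes 1 and 21, the farthest from the median gene number, were left out, r was 0.36 (permutation p = 0.11) and rho was 0.51 (permutation p = 0.020). The linear relation thus passed the threshold only with those chromosomes included, and the difference between r and rho was not tested.

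Within chromosomes, Twist1 peaks were concentrated in a few regions, several of them at chromosome starts or close to the last peak of a chromosome. The 10 densest 5-Mb windows held 1043 peaks, 29.2% of the list, out of 397 windows that held any peak. The window from 135 to 140 Mb of chromosome 9 held 197 peaks, and the part of that chromosome beyond 130 Mb held 341 of its 422. The first 5 Mb held 190 of the 331 peaks of chromosome 5, 181 of the 291 of chromosome 16, 81 of the 323 of chromosome 7 and 54 of the 367 of chromosome 1. On chromosome 20, 110 of 198 peaks lay beyond 60 Mb. Chromosome 13 had 43 of its 54 peaks, and chromosome 21 had 26 of its 34, in 1 window each, at 110 to 115 Mb and 45 to 50 Mb. The 1-Mb window with the most peaks ran from 1 to 2 Mb of chromosome 5 and held 103.

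Long stretches of other chromosomes held none or few. The longest interval between neighbouring peaks ran for 74.1 Mb on chromosome 4, from 3578963 to 77662194. An interval of 49.5 Mb on chromosome 2 ran from 170218870 to 219736133, and only 6 of the 118 peaks of chromosome 2 lay beyond 140 Mb. Chromosome 9 had 6 peaks in its first 75 Mb, chromosome 20 had 2 in its first 25 Mb, and chromosome 6 had 49 of its 58 peaks in the first 50 Mb. Assembly gaps were not taken out of these stretches, so part of their length may be unable to hold a peak.

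**Figure D3:**
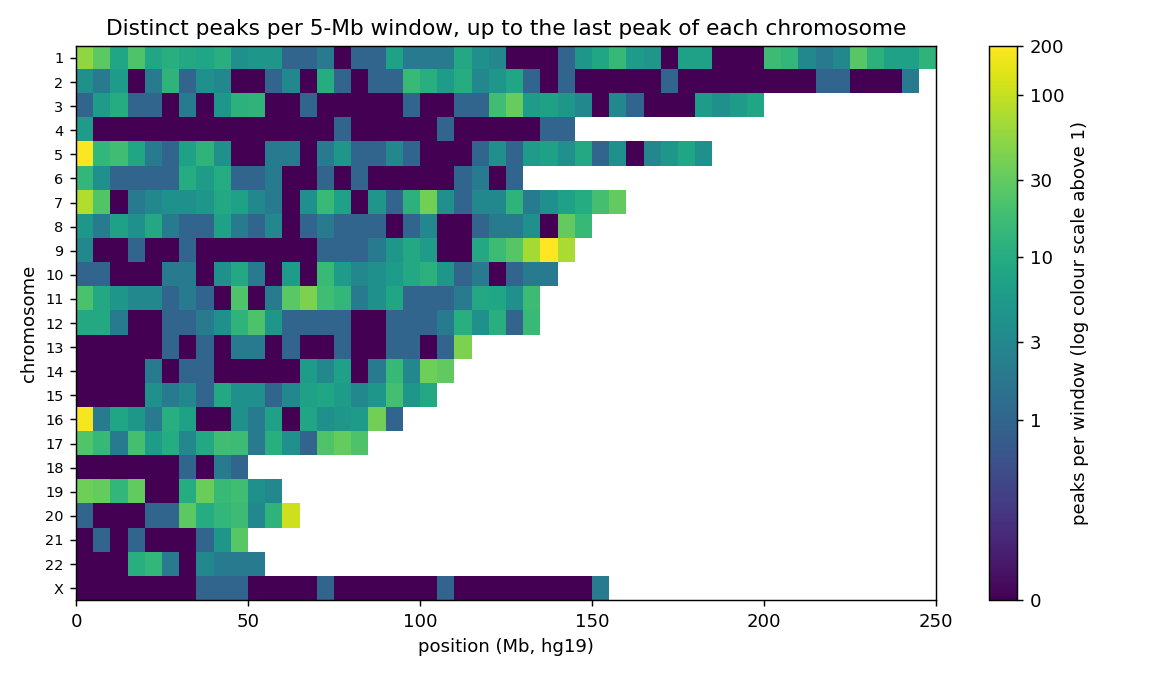
Number of distinct Twist1 peaks in each 5-Mb window (colour, log scale above 1) by chromosome (y axis) and position in Mb of hg19 (x axis), drawn up to the last peak of each chromosome. The brightest windows, with 197, 190 and 181 peaks, are at 135 to 140 Mb of chromosome 9 and at the start of chromosomes 5 and 16, while chromosomes 4, 18 and X are nearly empty.

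Peaks also lay close to one another at a finer scale. Of all peaks, 37.1% had another peak within 10 kb, against a mean of 3.87% (95% of draws 3.02 to 4.76%) when peaks were placed at random between the first and last peak of their own chromosome, a ratio of 9.59. The two-sided permutation p was 0.0002, the smallest that 10000 placements can give. Part of this ratio followed from the dense regions described above. When each peak was placed at random inside its own 1-Mb window, 22.7% of peaks had a neighbour within 10 kb (95% of draws 21.4 to 24.0%), a ratio of 1.63 with the same permutation p. Within 100 kb, 70.2% of peaks had a neighbour, against 31.5% by placement over the chromosome and 62.5% by placement inside the 1-Mb window.

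The last comparison related the length of peaks to where they lay, since the list gives no measure of strength. Whether length follows strength cannot be told from this list. Peaks in crowded regions were longer. The 878 peaks with 20 or more others within 500 kb had a median length of 254.5 bp (quartiles 203 and 347 bp), and the 763 peaks with at most 1 other had a median of 219 bp (192 and 276.5 bp). Across all peaks, which are not independent replicates, length and the number of neighbours within 500 kb had a Spearman's rho of 0.14 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). Ranked within each chromosome, rho was 0.12, with a permutation p of 0.0032 when lengths were shifted around each chromosome so that neighbouring peaks stayed together. In the 20 chromosomes with 30 or more peaks, rho ranged from -0.20 on chromosome 21 to 0.32 on chromosome 16 and was positive in 15.

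Among those 20 chromosomes, only chromosome 5 had peaks whose median length differed from that of the other chromosomes after Benjamini-Hochberg adjustment. Its peaks had a median of 259 bp, 30 bp longer than the 229 bp elsewhere (adjusted permutation p = 0.0002, two-sided). The permutation treats single peaks as independent, which nearby peaks are not, so this p-value may be too small. The longer median came with the dense first window of chromosome 5, where the 190 peaks had a median of 281 bp. The 141 peaks on the rest of chromosome 5 had a median of 236 bp, and did not differ detectably from those of other chromosomes (permutation p = 0.39).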

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

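The tests in this part were chosen after the repeats had been seen. The list names 489 of its 3570 positions (13.7%, Wilson 95% interval 12.6 to 14.9%) in more than 1 row, a feature that the main comparisons, which count each position once, do not use. Of these, 439 positions have 2 rows, 40 have 3, and 10 have 4 or more. The most, 13 identical rows, belong to a 182-bp peak on chromosome 5 (140263909 to 140264090), followed by 11 rows for a 200-bp peak on chromosome 17 (36350001 to 36350200).

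The tables argue against rows copied at random. Among 179 pairs of neighbouring peaks within 1 kb, both members were repeated in 33 and 1 member in 7, whereas shuffling the repeat marks within chromosomes gave a mean of 3.75 pairs and at most 14 in 10000 shuffles. The one-sided permutation p was 1e-04, the smallest these shuffles can give. In 31 of the 33 pairs the numbers of rows were equal. Since 439 of the 489 repeated positions have 2 rows, such matches are frequent in any case, and their number was not tested. They also argue against repeats marking longer peaks: repeated and single peaks both had a median of 232 bp, with a bootstrap 95% interval of the difference from -7 to 10 bp. One row per overlapping gene or transcript, left from an annotation step whose columns are now empty, is a candidate explanation. The share of repeated peaks rose with protein-coding genes per Mb over 23 chromosomes (Spearman's rho = 0.50, permutation p = 0.017; rho = 0.44, permutation p = 0.049, without chromosomes 17 and 19), though Pearson's r was 0.27 (permutation p = 0.20). No biological explanation was tested, and the authors' annotation itself was not analysed here.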

How the results depend on the processing

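Merging peaks within 1000 bp, fixed before the data were examined, left 3335 peaks and the same 5 chromosomes above and 10 below their share; all other alternatives in this part except the 100-kb distance were chosen after seeing the data. Keeping only peaks longer than the median left 1769. Calls per chromosome, 15 in all, fell to 6 (2 above, 4 below) with 1-Mb windows counted once. Fewer items were then counted, and dense regions weighed less. The number of windows is also capped by chromosome length, which raises ratios of gene-poor chromosomes and lowers those of gene-dense ones. Of the 4, chromosome 19 has too few windows to reach its gene share, so its call says nothing. With 100-kb windows 7 were above and 6 below. With all genes as the reference 22 of 23 chromosomes were called, 8 above and 14 below. Chromosomes 11, 17 (1.33) and 19 joined those above, and chromosomes 8, 13 (0.58 against 0.89), 14, 15 and 21 those below. Chromosome 8 was also called below with every row counted and with longer peaks only, chromosome 15 with every row counted, and chromosomes 1 and 17 above with 100-kb windows. Chromosome 1 turned to a ratio of 1.17 with 100-kb windows. Chromosome 3 turned to 1.07 and chromosome 10 to 1.06 with 100-kb windows, and to 1.19 and 1.25 with 1-Mb windows. Chromosomes 11 and 19 both turned to 1.20 with all genes as the reference. Their peaks, 229 and 195, stayed the same there. These 2 turns thus follow from a smaller share of all genes than of protein-coding genes. The cause of the other turns was not tested. The clustering ratio stayed above 1 with p = 0.0002 by permutation under 7 of 7 alternatives, from 1.12 (100 kb, inside 1-Mb windows) to 15.1 (peaks longer than the median). The alternatives that need fold, p-values, genes or sequence were not run. No depth is known, and with 1 ChIP library a region without peaks cannot be told from one sequenced too thinly to show any. No paired analysis was possible because each group has 1 library and the input has no values here.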

Other observations

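Of the tests in this part, the one of merged peaks was set before its result was seen and the others after. The uneven spread over chromosomes is the pattern most worth a second look: peaks per protein-coding gene differ from 0.046 times the mean on X to 3.03 times on chromosome 9. Copy number is one candidate cause, since HepG2 is known to carry extra copies of several chromosomes, and background knowledge named chromosomes 2, 14, 16, 17 and 20. As the whole cause, whole-chromosome gains of these are argued against. Chromosome 2 had 0.53 times its share (0.44 to 0.63). Chromosome 7, which is not among the 5, had 1.93 times its share and stayed at 1.44 without the peaks of its densest 5-Mb window. With each 1-Mb window counted once, chromosome 2 was at 0.99 (0.76 to 1.26) and chromosome 7 at 1.74. That count follows chromosome length and not genes, so neither of these window values decides the question. A part played by such gains was neither shown nor excluded. Of the 5, 2 were called above their share and 1 below, and their pooled ratio was 1.18. Their geometric mean ratio was 1.70 times that of the other 17 autosomes (exact permutation p = 0.27, two-sided), and 1.27 times (exact permutation p = 0.43) without the nearly empty chromosomes 4 and 18. Gene density of whole chromosomes stays open, with a Spearman's rho of 0.28 with peaks per gene (permutation p = 0.20, 23 chromosomes) and a Pearson's r of 0.046 (permutation p = 0.83), because chromosome averages may blur differences within a chromosome. Gains of single segments, GC content of those ends, the handling of the input in peak calling and Twist1 binding itself were not tested.

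A second pattern is that 37.1% of peaks had a neighbour within 10 kb. Megabase density as the whole cause does not account for it (ratio of 1.63 to placement inside the own 1-Mb window). Nor do broad regions split by the peak caller at gaps of up to 1 kb, as the whole cause. After peaks within 1 kb were merged, the ratio to that placement was 1.54 (permutation p = 0.0002). Broad regions split at gaps between 1 and 10 kb would survive the merging, so splitting at those distances was not tested. Clusters of bound sites at single loci, and local GC content or mappability, may each contribute, and neither was tested.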
